A study of Drosophila melanogaster with 36 samples.

How the data were processed

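The series measured RNA by sequencing in sucrose gradient pools of Drosophila melanogaster embryos of 2 genotypes, wild type (w1118) and orb2-delta-zz, at 0-1h, 1-2h and 2-3h after egg laying. Lysates were run on a gradient, and pools 1 and 3 of each gradient were sequenced after removal of ribosomal RNA, as stranded libraries. Each of the 12 combinations of genotype, time and pool had 3 replicates, so there were 36 libraries, and the columns of the tables were matched to the samples through the names given in the labels. No pair of libraries was identical.

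The deposited normalized counts, a signal per gene and library, were made by the authors by dividing estimated gene counts by DESeq2 normalization factors, separately for each time. The authors' notes name Trim Galore 0.6.5, Salmon 1.9.1 and DESeq2 1.42.1, and the genome build is not given in the sources used here. The deposited TPM values were made by the authors as transcripts per library scaled to a common total, and summed to 983911 to 998618 in each library over the listed genes. Each table listed only genes with a value above 0 in all 12 libraries of its time, so a gene silent in 1 library is missing from it. The ratio of normalized count to TPM was constant per gene up to 1 factor per library (SD of its log2 0.00701), so the factors correct for gene length as well as library size, and whole read counts are not recovered. Depth was therefore estimated from the step between low values of genes with transcripts of at least 1500 nt, as 19.1 to 45.8 M reads, and counting intervals were not computed. Per library, 66.3% to 100% of these low values lay near a whole number of steps. Small nuclear and nucleolar RNAs took 7.80% to 23.5% of the TPM in pool 1 and 0.710% to 1.43% in pool 3. Gene symbols and positions came from Ensembl release 115 (BDGP6), and the 71 of 10226 gene IDs without a symbol there were tested but not named.

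Tests used limma 3.58.1 in R 4.3.3, with tables prepared in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1) and figures drawn with matplotlib 3.10.9. For each time, log2(normalized count + 1) of genes with a mean of at least 10 was fitted with a mean for each of the 4 groups and a spread shared between them (limma with trend), and 4 contrasts were tested: orb2-delta-zz minus wild type in pool 1, the same in pool 3, the genotype difference in the pool 3 to pool 1 ratio (the interaction), and the ratio in wild type. Since the normalized counts were scaled separately per time, the change from 0-1h to 2-3h in wild type was tested on log2(TPM + 1) of genes listed at all 3 times with a mean TPM of at least 1, over the 18 wild-type libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, in two-sided tests. Overlaps of calls between times were compared with the number expected of independent calls by a one-sided hypergeometric test. The tests were also run on simulated data made from these libraries, in which 58.2% of the genes changed by 1.5-fold, 82.8% of those changed by 2-fold and 95.5% of those changed by 4-fold were called in pool 3 at 0-1h, and 5.63%, 33.8% and 81.2% at 2-3h. For the interaction the shares were 15.9%, 59.0% and 78.6% at 0-1h and 0%, 8.20% and 51.2% at 2-3h. Few genes were changed and all others had no genotype difference. In pool 3, 167 genes were called at 0-1h and 82 at 2-3h, against 571 and 1403 in the data. The share called after adjustment depends on how many genes differ, so it may be another one in the data. The simulated noise was independent between libraries and genes. It lacks the deviations that pools 1 and 3 of a gradient share (correlations of 0.39 to 0.83 at 2-3h). The shares therefore describe the fit without the gradient as a block and are no limit of the design.

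Gene lists were tested against the other genes with camera at a preset inter-gene correlation of 0.01, for lists with at least 5 tested members, with adjustment over all lists, times and contrasts. The lists were Orb2 targets named in earlier work on neurons and testis, RNA-binding and mRNA-decay factors, PNG kinase and the syncytial cell cycle, germ plasm, classic maternal transcripts, first zygotic transcripts, late-embryo markers, egg-shell and follicle-cell markers, markers of adult fat body, gut and sperm, heat-shock genes, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, translation factors, nuclear-encoded oxidative phosphorylation, mitochondrially encoded RNAs, the proteasome, replication-dependent histones, histone variants, small nuclear and nucleolar RNAs, long noncoding RNAs, and cellularisation and the cytoskeleton. Camera was repeated with an estimated correlation, where no list call held (0). Fry was run as well, which tests a list against no change and not against the other genes.

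The genes named are the 5 highest and 5 lowest log2 differences among called genes with a mean of at least 100 normalized counts and no overlap between the groups, for each time and contrast. For the change with time they are the 10 highest and 10 lowest with a mean TPM of at least 10 in each pool. From each list, up to 4 members with the largest mean and up to 4 past the threshold could be named, and orb2 always. A gene that the rule picks is not reported here. The comparisons, their tests, the lists, this rule and the alternatives were fixed before the data were examined. Alternatives that leave out 2 gradients together, other splits of the samples and the tests of low read numbers, of chromosome 3, of late embryos and of 2 wild-type gradients were added afterwards.

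The alternatives were array weights, log2(value + 8), a mean of at least 100 or no filter, quantile normalization, upper-quartile scaling, log2(TPM + 1), only the 6 libraries compared, the replicate number or the gradient as a block, a fold of at least 1.5, and leaving out each gradient in turn. At 1-2h the column names number replicate 1 differently in the genotypes, so the replicate block joins gradients of unlike number there. For the change with time the alternatives were log2(TPM + 0.1), a mean TPM of at least 10, no filter, both scalings, the block, only the 6 libraries compared and leaving out each gradient. Raw reads, transcript isoforms and fractions of the gradients other than pools 1 and 3 were not analysed here.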

Results

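RNA was measured in sucrose gradient pools of Drosophila melanogaster embryos collected 0-1h, 1-2h and 2-3h after egg laying. In these hours RNA supplied by the mother is cleared and the embryo's own transcription starts. The embryos were wild type (w1118, the stock used before injection) or carried orb2-delta-zz, a deletion of the zinc-binding ZZ domain of ORB2, an RNA-binding protein of the CPEB family. Pools 1 and 3 of each gradient were sequenced from 3 gradients per genotype and time, which gave 36 libraries in 12 groups of 3. The labels do not say which part of the gradient a pool covers. The library totals lay between 2.16e+07 and 4.73e+07 normalized counts (median 3.60e+07), and the estimated depth lay between 19.1 and 45.8 M reads (median 34.3). The lowest estimate, that of orb2-delta-zz pool 3 replicate 1 at 0-1h, is uncertain. Only 70.6% of its low values lay near a whole number of steps (median of all libraries 97.1%). The other libraries of pool 3 at 0-1h gave 31.2 to 39.1 M reads. The authors' tables listed 7746 genes at 0-1h, 8723 at 1-2h and 10091 at 2-3h. In what follows, log2 differences between genotypes are orb2-delta-zz minus wild type and are given ± SE, and group means are normalized counts ± SD, n = 3.

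The edited gene, orb2 (FBgn0264307, BDGP6 chromosome 3L, 8937100 to 8954463, minus strand), was detected in every library, so RNA from the locus was present in both genotypes. At 0-1h it had 1499 ± 487 normalized counts in wild-type pool 1 and 1178 ± 129 in orb2-delta-zz, with 2291 ± 34.7 and 1859.7 ± 80.2 in pool 3. Neither difference passed the test (log2 difference -0.30 ± 0.18 in pool 1, adjusted p = 0.395). Those at 1-2h did not pass it either (-0.07 ± 0.22, adjusted p = 0.882, in pool 1). At 2-3h orb2 was higher in orb2-delta-zz in pool 1, with 849.9 ± 385 against 391 ± 100.3 normalized counts (log2 difference 1.06 ± 0.32, adjusted p = 0.0315). The difference of 0.61 in pool 3 did not pass the test (adjusted p = 0.205). The pool 1 call at 2-3h was lost without orb2-delta-zz replicate 3 (0.72), without wild-type replicate 1 (0.83) or 3 (1.21), with log2(TPM + 1) (0.66), and with only the 6 libraries compared (1.06). The genotype difference in the pool 3 to pool 1 ratio of orb2 did not pass the threshold at any time (interaction 0.00 at 0-1h, -0.14 at 1-2h and -0.45 at 2-3h, adjusted p = 0.767 at 2-3h).

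The first comparison asked which RNAs differed between orb2-delta-zz and wild type at 0-1h, when the embryo holds almost only maternal RNA. The first zygotic transcripts were lower in orb2-delta-zz. Of 60 measured members of that list, 27 were lower in pool 1 and 28 in pool 3, and none was higher. Among them were bnk, which acts in cellularisation (log2 difference -1.63 ± 0.34 in pool 1, -2.05 in pool 3), and halo, which directs lipid droplet transport (-2.22 ± 0.36, -2.29). The SOX factor gene D (-1.63 ± 0.36, -1.81) and Z600, which delays mitosis (-1.75 ± 0.38, -2.36), were lower too. The largest single differences were in other genes. Arc1 (FBgn0033926, 2R, 14357927 to 14360297), which encodes a capsid-forming protein related to retrotransposon Gag, was higher in both pools. It had 26.8 ± 18.2 normalized counts in wild type and 9454 ± 1080.3 in orb2-delta-zz in pool 1 (log2 difference 8.76 ± 0.54, adjusted p = 1.3e-06). In pool 3 it had 10.6 ± 4.08 and 1633 ± 284 (7.18).

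The other genes at the top at 0-1h were CG12560 (FBgn0031974, 2L, 8008302 to 8009477; 6.86 in pool 1 and 7.39 in pool 3) and CG5096 (FBgn0032235, 2L, 10382263 to 10384723; 6.61 and 5.87). Next came CG3104 (FBgn0031473; 6.20 and 5.28) and CG17470 (FBgn0032869; 5.83 and 5.30). At the bottom was dati (FBgn0262636, chromosome 4, 375640 to 395605), a zinc-finger transcription factor gene. It had 1699 ± 58.4 normalized counts in wild-type pool 1 and 11.8 ± 7.21 in orb2-delta-zz (-7.19 ± 0.53, adjusted p = 6.7e-06). CG34334 (FBgn0263829, X, 22872812 to 22875367) went from 811 ± 9.92 to 10.5 ± 1.62 (-6.16 ± 0.20, adjusted p = 7.4e-09). Also low were CG13982 (FBgn0031811; -4.35 in pool 1), lncRNA:CR43960 (FBgn0264675; -3.98) and tut (FBgn0052364, 3L, 8209577 to 8210743; -4.33), whose protein represses translation in the male germ line. GILT3 (FBgn0039098, 3R, 23677358 to 23678421), a lysosomal thiol reductase gene, fell from 352 ± 38.2 to 12.5 ± 2.76 in pool 3 (-4.72).

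Maternal and germ-plasm transcripts moved little at 0-1h. One classic maternal transcript of 28 was higher in pool 1, cort, an activator of the anaphase-promoting complex in meiosis (0.61 ± 0.09). In pool 3 cort (0.78) and the oocyte ligand gene grk (0.41) were higher (list adjusted p = 0.68 and 0.76). Of the germ-plasm list, piwi, whose protein silences transposons, was higher (0.66 ± 0.09 and 0.69) and krimp, of the same pathway, was lower in pool 1 (-0.81 ± 0.12). None of the 8 measured Orb2 targets named in earlier work on neurons and testis passed limma's test at 0-1h. Over all tested genes, 1593 in pool 1 and 1209 in pool 3 had an unadjusted p under 0.05. Of the proteasome subunit mRNAs 3 were lower in pool 1, among them Prosalpha1 (-1.39). The late-embryo markers, a list of genes chosen as active in older embryos, had median log2 differences of 0.96 in pool 1 and 0.69 in pool 3 over 10 genes, with none called. Without orb2-delta-zz replicate 1 the medians were -0.31 and -0.92, with 3 called lower in pool 3. Their levels stood apart in orb2-delta-zz replicate 1, where the median lay 3.48 above the mean of pool 1 and 4.20 above that of pool 3.

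In all, 756 of 7533 genes differed between genotypes in pool 1 at 0-1h (423 higher and 333 lower) and 571 in pool 3 (335 and 236). The 3 values of each genotype did not overlap for 23.3% of genes in pool 1 and 26.4% in pool 3, where chance gives 10%. The zygotic list was lower by camera in both pools (median -1.44, adjusted p = 6e-20, and -1.60, adjusted p = 2.8e-32). These became adjusted p = 0.95 and 0.78 with an estimated correlation. Adjusted over the list alone, 44 and 46 members were lower. With log2(TPM + 1) the split was 86 higher and 129 lower in pool 1 and 139 and 191 in pool 3. It moved the median of all genes in pool 1 by -0.13, and the zygotic median relative to it was -0.60. TPM differs from the normalized counts by 1 factor per gene and 1 per library, which would leave that value nearly unchanged. The added 1 and the TPM filter remain, and their shares were not tested. Zygotic medians per library in pool 1 were low, at 32.7 to 152 normalized counts. The zygotic calls in pools 1 and 3 numbered 38 and 49 without orb2-delta-zz replicate 1, 14 and 15 without its replicate 2 and 8 and 17 without its replicate 3. They numbered 5 and 8 without wild-type replicate 2 and 11 and 12 without wild-type replicate 3. The counts of all genes without 1 gradient ran from 346 (wild-type replicate 2) to 1150 (orb2-delta-zz replicate 1) in pool 1 and from 256 to 884, without the same gradients, in pool 3.

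**Figure D1:**
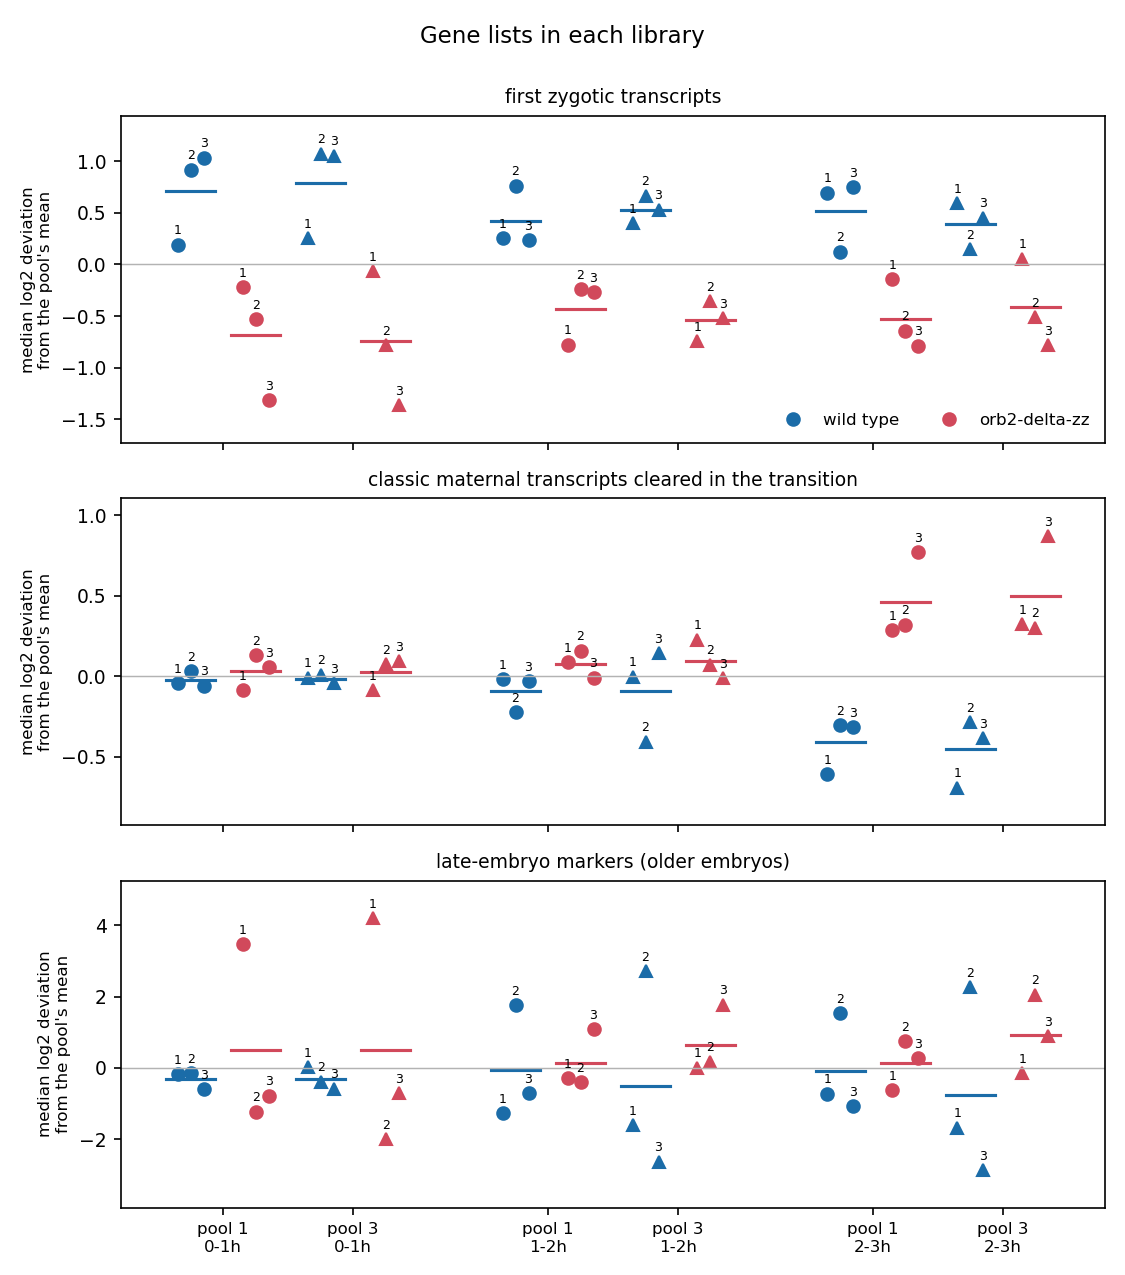
Median log2 deviation of the first zygotic, classic maternal and late-embryo lists from the mean of their pool and time in each library (circles pool 1, triangles pool 3, numbers the replicates, bars the group means). At 0-1h the zygotic list lay between 0.19 and 1.03 in wild-type pool 1 and between -1.31 and -0.22 in orb2-delta-zz pool 1.

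At 1-2h the same question gave the same direction for the zygotic genes. The list was lower in orb2-delta-zz in 37 of 61 members in pool 1 and in 49 of 61 in pool 3, and none was higher. Examples in pool 1 were halo (-1.20 ± 0.36) and the segmentation and sex-determination genes ftz (-0.69 ± 0.18), run (-0.76 ± 0.17) and sc (-0.66 ± 0.19). Examples in pool 3 were bnk (-0.96), D (-1.20), Z600 (-1.09) and term (-1.03). Transcripts of the mitochondrial ribosome were higher in 18 of 71 members in pool 1 and 6 in pool 3. They included mRpL30 (1.29 ± 0.18), mRpL15 (0.90) and mRpL12 (0.55) in pool 1 and mRpL54 (1.25) in pool 3. Long noncoding RNAs leaned lower, with 31 of 268 lower and 13 higher in pool 1. Among the lower were roX1, an RNA of the dosage compensation complex (-1.33 ± 0.24 in pool 1, -1.18 in pool 3), and marge (-1.26 and -1.41).

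Arc1 was again at the top at 1-2h, with 218.7 ± 249 normalized counts in wild-type and 10643 ± 2823 in orb2-delta-zz pool 1 (6.20 ± 0.64, adjusted p = 3.5e-05). CG31683 (FBgn0051683, 2L, 20447734 to 20449964) rose from 22.7 ± 1.99 to 1648 ± 78.6 in pool 1 (6.12 ± 0.69) and from 24.2 ± 34.7 to 2515 ± 116 in pool 3 (7.72). It was followed by CG5096 (5.86), CG17470 (5.77) and CG3104 (4.84) in pool 1 and CG12560 in pool 3 (6.73). CG34334 went from 755 ± 230.0 to 5.84 ± 2.65 in pool 1 (-6.80 ± 0.36, adjusted p = 9.1e-08). Next were dati (-6.03), CG13982 (-4.0), tut (-3.97) and GILT3 (-3.52), and in pool 3 lncRNA:CR43960 (-3.83). Nap1, a maternal histone chaperone transcript, was higher in both pools (0.86 and 0.87), and piwi was higher again (0.87 and 0.82). Of the 9 Orb2 targets, tutl, an immunoglobulin-superfamily gene (-1.0 in pool 1, -1.14 in pool 3), and the eye-development gene eya (-1.78, -1.85) were lower. The list as a whole had an adjusted p of 0.0035 in pool 1 (0.95 with an estimated correlation) and 0.095 in pool 3. The Hsp26 chaperone mRNA was higher (1.07 and 1.00). Late-embryo markers had medians of 0.40 and 1.38 over 19 genes, with elav, a neuronal gene, lower (-1.18 ± 0.32 and -1.22). At 2-3h elav had 8639, 5786 and 7790 normalized counts in wild-type pool 3, replicates 1 to 3, so it did not mark late embryos alone. The list stood apart in wild-type replicate 2 (1.76 and 2.72 above the mean of pool 1 and pool 3) and in orb2-delta-zz replicate 3 (1.09 and 1.78). Without wild-type replicate 2 the medians were 1.20 and 3.38, with 4 and 12 members called higher. Without orb2-delta-zz replicate 3 they were -0.02 and 0.94, and without wild-type replicates 1 and 3, each left out alone, -0.01 and 0.05 in pool 1 and 0.65 and 0.22 in pool 3.

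Of 8294 genes tested at 1-2h, 550 were higher and 398 lower in pool 1, and 293 higher and 418 lower in pool 3. The genotypes did not overlap for 30.1% and 28.6% of genes. Camera called the zygotic list lower (median -0.83, adjusted p = 1.5e-32, and -1.04, adjusted p = 8.2e-44; 0.75 and 0.68 with an estimated correlation). Adjusted over the list alone, 54 and 59 members were lower. The mitochondrial ribosome list was called higher (0.44, adjusted p = 7.7e-09, and 0.30, adjusted p = 5.2e-07; 0.999 in both with an estimated correlation). Adjusted over the list alone, 30 of its members were higher in pool 1. The long noncoding list was called lower (-0.23, adjusted p = 5.1e-05, and -0.28, adjusted p = 1.8e-05; 0.78 and 0.75 with an estimated correlation). The median of all genes in pool 1 moved by -0.12 with quantile normalization and by -0.15 with upper-quartile scaling, which gave 541 higher and 701 lower genes. Relative to all genes the zygotic median was -0.94 and the mitochondrial ribosome median 0.33 under upper-quartile scaling. As this scaling changes each library by 1 factor, it could hardly alter values relative to all genes. Without wild-type replicate 2 and orb2-delta-zz replicate 3, a test chosen after the data were seen, 19 zygotic members were lower in pool 1 and 37 in pool 3. With 1 gradient left out, 17 (orb2-delta-zz replicate 1) to 31 zygotic members were lower in pool 1, with 23 without orb2-delta-zz replicate 2 or wild-type replicate 1 and 21 without wild-type replicate 2, and 37 to 45 in pool 3. Counts without 1 gradient ran from 423 (orb2-delta-zz replicate 2) to 833 in pool 1 and from 422 (orb2-delta-zz replicate 1) to 794 in pool 3.

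At 2-3h wild-type embryos clear maternal RNA and transcribe their own genome widely. The zygotic list was lower in 44 of 61 members in pool 1 and 25 of 61 in pool 3, with none higher. The number of calls depended on single gradients, the medians less so. Without orb2-delta-zz replicate 2 or 3 or wild-type replicate 1 or 3, 23, 20, 15 and 22 were lower in pool 1 and 2, 2, 5 and 4 in pool 3, where the medians were -0.82, -0.67, -0.79 and -0.84 (-0.87 with all gradients). Without orb2-delta-zz replicate 1 and wild-type replicate 2, each left out alone, 44 and 51 were lower in pool 3, and 59 or 60 of 61 members were below 0 in each pool in all of these. Transcripts of the maternal and germ-plasm lists were higher in orb2-delta-zz. Classic maternal transcripts were higher in 15 of 29 members in pool 1 and 19 in pool 3 (9 and 8 without orb2-delta-zz replicate 3, 9 and 6 without wild-type replicate 1, and 12 in pool 3 without orb2-delta-zz replicate 2 or wild-type replicate 3), and sala was lower in pool 1 (-1.63 ± 0.37). They included the chaperone mRNA Hsp83 (1.30 ± 0.23 in pool 1), Nap1 (1.32 ± 0.16 and 1.35), the posterior determinant osk (1.40 ± 0.40 and 2.04), the translational repressor smg (1.16 in pool 3) and CycB (1.10 in pool 3). Of 26 germ-plasm genes, 15 were higher in pool 1 and 16 in pool 3 (10 in each without wild-type replicate 1), and none was lower. They included swa (2.02 ± 0.37 and 2.28), gcl, which is needed for germ-cell formation (1.49 ± 0.35 and 1.23), and bru1 (1.45 ± 0.33 and 2.15).

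The zygotic members lower at 2-3h included the cellularisation gene slam (-0.95 ± 0.20), Sxl, the switch of sex determination (-0.95 ± 0.26), Z600 (-1.05 ± 0.24) and D (-1.17 ± 0.21) in pool 1, and halo (-1.03) and term (-0.90) in pool 3. Oxidative phosphorylation mRNAs were higher in 27 of 66 members in pool 1 and in 3 in pool 3, and pool 1 examples were ATPsynbeta (1.41 ± 0.15), UQCR-C1 (0.74) and ATPsynF (0.85). Proteasome mRNAs were higher in 12 of 32 members in pool 1, with Rpn5 (1.05 ± 0.24) and Rpt1 (0.73). In the same pool 22 of 71 mitochondrial ribosome mRNAs were higher and 1 lower. RNA-binding and decay factors were higher in 8 of 29 members in pool 1, including tral (1.02), me31B (0.86) and twin (0.76). In pool 3 they were higher in 5, including cup (1.14) and orb (2.04), the paralog of orb2. Of the Orb2 targets, orb2 and orb (1.74 ± 0.41) were higher in pool 1 and 4 were lower, among them neur (-0.71), mura (-0.78) and tutl (-1.07). In pool 3 orb alone was called. Long noncoding RNAs were lower in 77 of 416 members and higher in 15 in pool 1 (roX1 -1.14 ± 0.30). Among heat-shock genes 6 of 17 were higher in pool 1, with Hsp26 at 2.36 ± 0.26 (1.25 in pool 3) and the co-chaperone gene DnaJ-1 at 1.15.

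Dscam4 (FBgn0263219, 3L, 8238647 to 8282398), an immunoglobulin-superfamily adhesion gene, fell from 3319 ± 671 to 35.8 ± 26.1 normalized counts in pool 3 at 2-3h (-6.73 ± 0.46, adjusted p = 8.2e-06) and from 332 ± 104 to 11.1 ± 3.64 in pool 1 (-4.77 ± 0.46). Other low genes were CG34334 (-4.61 and -5.45), DIP-theta (FBgn0051646), a cell-surface immunoglobulin gene (-4.55 and -4.01), CG11380 (FBgn0040359; -4.41 in pool 1), CG4563 (FBgn0035006; -4.12 in pool 1) and the noncoding CR32010 (FBgn0052010, chromosome 4, 12640 to 25054). The last went from 821 ± 75 to 28.3 ± 8.13 in pool 3 (-4.84). CG31683 rose from 36.4 ± 12.8 to 1801 ± 117 in pool 1 (5.65 ± 0.58, adjusted p = 0.000138) and CG12560 was at the top in pool 3 (7.10). Arc1 had 1211 ± 1721 against 19220.0 ± 2264 in pool 1 (5.87 ± 1.40, adjusted p = 0.0121). That call was lost without orb2-delta-zz replicate 3 or wild-type replicate 1. In pool 3 Arc1 was also higher (4.79, adjusted p = 0.0384), a call lost without any single orb2-delta-zz replicate or without wild-type replicate 1. The glutathione S-transferase gene GstE8 (FBgn0063492; 3.68), CG4267 (FBgn0264979; 3.51) and CG9896 (FBgn0034808; 3.34) followed in pool 1, and the calcineurin subunit gene CanB2 (FBgn0015614; 3.37) and rost (FBgn0011705; 3.07) in pool 3.

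Late-embryo markers had medians of 0.06 in pool 1 and 1.71 in pool 3 at 2-3h over 22 genes, with Fas2 alone called (-0.93 ± 0.26 in pool 1). They were far higher in wild-type replicate 2 (1.53 and 2.27 above the mean of pool 1 and pool 3) than in wild-type replicates 1 (-0.72 and -1.68) and 3 (-1.07 and -2.86). In orb2-delta-zz replicate 2 they stood at 0.75 and 2.05. The muscle actin mRNA Act57B had 388, 13157 and 160.0 normalized counts in wild-type pool 1, replicates 1 to 3, and 1364, 13101 and 3785 in orb2-delta-zz. Without wild-type replicate 2 the markers were higher in orb2-delta-zz, by medians of 0.92 and 3.27, with 7 and 13 called. Without orb2-delta-zz replicate 2, wild-type replicate 1 or wild-type replicate 3 the medians in pool 1 were -0.03, -0.12 and -0.21, and those in pool 3 were 1.11, 1.15 and 0.62. Without wild-type replicates 1 and 3, a test chosen after the data were seen, the zygotic medians were -0.64 and -0.58 with 5 and 6 members called. The maternal medians in that test were 0.86 and 0.75 with 2 called in each pool, and the late-embryo medians -1.21 and -1.26, since the gradient left was the one rich in late-embryo RNA. Without the gradient of each genotype with the most late-embryo RNA, replicate 2 in both, also chosen after the data were seen, 40 zygotic members were lower in pool 1 and 7 in pool 3.

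Of 9554 genes tested at 2-3h, 1374 were higher and 906 lower in pool 1 and 928 and 475 in pool 3. With the replicate number as a block, as replicate 2 of both genotypes held late-embryo RNA, 3950 and 3301 genes were called. Deviations from the group means in replicates 1 to 3 correlated between genotypes at 0.62, 0.63 and 0.22 in pool 1. In pool 3 they did so at 0.76, 0.74 and -0.01. Pairs of unlike replicate number ran from -0.66 to 0.33 in pool 1 and from -0.79 to 0.65 in pool 3. The fit without the block leaves this pairing out. The genotypes did not overlap for 36.8% and 35.3% of genes. By camera the lists differed as follows, each with a p of 0.95 to 0.999 with an estimated correlation. The zygotic list was lower (median -1.06, adjusted p = 1.3e-18, and -0.87, adjusted p = 3.6e-16; 55 and 50 members lower and, in pool 3, 1 higher, adjusted over the list alone). The maternal list was higher (0.98 in both, adjusted p = 7.4e-06 and 7.6e-09; 19 and 20 higher, adjusted over the list alone), as were germ plasm (0.98, adjusted p = 2.7e-06, and 0.87, adjusted p = 1.7e-08; 18 and 19 higher, adjusted over the list alone). Also higher were RNA-binding and decay factors (0.25, adjusted p = 0.025, and 0.30, adjusted p = 0.013) and heat-shock genes (0.65, adjusted p = 0.018, and 0.97, adjusted p = 0.026). In pool 1 but not in pool 3 the test called oxidative phosphorylation (0.51, adjusted p = 2.6e-08, against -0.03, adjusted p = 0.96), the proteasome (0.38, adjusted p = 5.4e-05, against 0.05, adjusted p = 0.89). The same held for the mitochondrial ribosome (0.45, adjusted p = 3.9e-07, against 0.17, adjusted p = 0.095). The long noncoding list was lower in both (-0.67, adjusted p = 2.6e-07, and -0.59, adjusted p = 1.8e-07). The split in pool 1 was 1482 higher and 1634 lower with quantile normalization and 1242 and 1958 with upper-quartile scaling. The latter moved the median of all genes by -0.14 and gave 933 and 1273 in pool 3. Counts without 1 gradient ran from 883 (wild-type replicate 1) to 3169 in pool 1 and from 376 (wild-type replicate 1) to 3172 (wild-type replicate 2) in pool 3.

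Whether the same genes differed at each time was asked in libraries that share no sample. In pool 1, 243 genes were higher at both 0-1h and 1-2h, where 30.6 were expected of independent calls. Another 139 were lower (16.2 expected), while 2 went opposite ways. From 1-2h to 2-3h the shared genes numbered 242 higher (90.9 expected) and 212 lower (37.3 expected), with 10 opposite. From 0-1h to 2-3h they numbered 143 higher (75.7 expected) and 123 lower (27.8 expected), with 33 opposite (9 in pool 3). Pool 3 shared 178 higher and 137 lower genes between 0-1h and 1-2h (12.8 and 11.6 expected) with none opposite. Across genes, which are not independent replicates, the differences at 0-1h and 1-2h correlated at 0.77 in pool 1 and 0.82 in pool 3, those at 1-2h and 2-3h at 0.57 and 0.66, and those at 0-1h and 2-3h at 0.38 and 0.47. Of 7456 genes tested at every time, 95 differed in the same direction at all 3 times in both pools, 58 higher and 37 lower.

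Among these 95 recurrent genes the highest mean log2 differences were those of Arc1 (6.35), CG12560 (5.84), CG5096 (4.64) and CG17470 (4.22). The lowest were those of CG34334 (-6.00), dati (-4.63), GILT3 (-3.73) and tut (-3.68). Further members, chosen after their values were seen, were GstE1, GstE7 and GstT3 of the glutathione S-transferases (3.36, 2.22 and 1.65) and the glucuronosyltransferase genes Ugt50B3 (3.36) and Ugt35A1 (2.30). The secreted growth factor gene Idgf3 (3.33) and the virus-response gene vir-1 (2.92) were higher as well and chosen in the same way. The lower ones, chosen in the same way, included the piRNA precursor RNA flam (-2.10), the phosphatase gene Ptp61F (-1.91), insc, which orients cell division (-2.16), and the zygotic genes sna (-1.06) and sc (-1.27). The recurrent genes lay on 2L (24), 2R (27), 3L (10), 3R (11), X (17) and chromosome 4 (6). Chromosome 4 thus held 6.32% of them against 1.01% of tested genes, and chromosome 3, which carries orb2, held 22.1% against 43.4%.

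**Figure D2:**
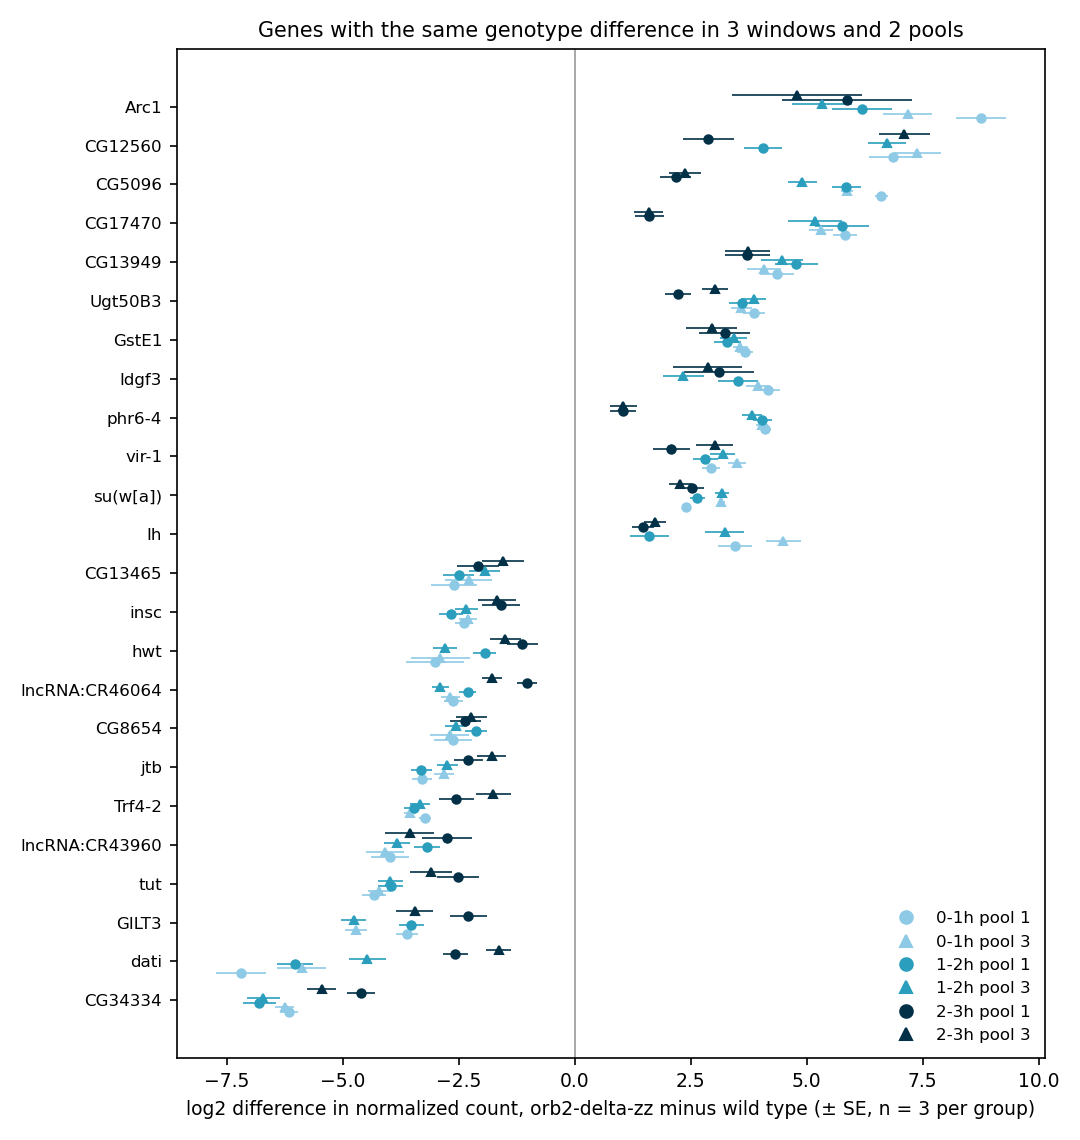
Log2 difference between orb2-delta-zz and wild type in pool 1 and pool 3 at each time (± SE) for the 12 recurrent genes with the highest and the 12 with the lowest mean. The means ran from -6.00 (CG34334) to 6.35 (Arc1).

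The comparison closest to translation asked whether the distribution of an RNA between the pools, its pool 3 to pool 1 ratio, differed between the genotypes. Some of the genes that did so shifted at more than 1 time. CG6180 (FBgn0032453, 2L, 12707661 to 12708680) went from 1039.9 ± 291 and 4440.1 ± 570.1 in pools 1 and 3 of wild type to 5257 ± 549 and 2562 ± 281 in orb2-delta-zz at 0-1h (-3.16 ± 0.26, adjusted p = 0.000546). Its difference was -3.70 ± 0.28 at 1-2h and -2.33 ± 0.24 at 2-3h. Tgt (FBgn0031321, 2L, 1184065 to 1185698), which encodes the queuine tRNA modification enzyme, had a higher ratio at 0-1h (1.72 ± 0.17) and 1-2h (2.56 ± 0.28). Sting (FBgn0033453, 2R, 9842686 to 9845512), of the innate immune response, had a lower one at 0-1h (-1.73 ± 0.18).

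At 1-2h the ratio was also lower for Hen1 (FBgn0033686, 2R, 12145710 to 12152752), the methyltransferase of small silencing RNAs. It had 98.1 ± 9.69 and 870.0 ± 86.9 normalized counts in wild type and 258 ± 35.4 and 464 ± 20.3 in orb2-delta-zz (-2.28 ± 0.23). The ratio of ecd, which acts in splicing and ecdysone supply (FBgn0000543), was lower too (-2.08 ± 0.24). At 2-3h the mean level of GstE8 went from 47.8 ± 6.25 to 621 ± 54.2 in pool 1 and from 53.3 ± 10.8 to 96.7 ± 27.1 in pool 3 (-2.84 ± 0.38, adjusted p = 0.0201). Both 0-1h and 1-2h had 11 genes called, each in the same direction at both times, where 0.208 were expected. Among them were CG17568, CG18476, CG1902, CG6180, CG9356, Rab3GAP1, Sting, Tgt, dnt and p24-1. Of 3 genes called at both 0-1h and 2-3h, 2 went in the same direction. Across genes the ratio differences correlated at 0.468 between 0-1h and 1-2h and at 0.027 between 0-1h and 2-3h. CG6180 was called in the same direction at all 3 times. Lists with a lower ratio in orb2-delta-zz at 2-3h were oxidative phosphorylation (median -0.48, adjusted p = 2e-12, with ATPsynbeta at -1.42 ± 0.21) and the proteasome (-0.42, adjusted p = 1.7e-06; 3 members lower when adjusted over the list alone). The mitochondrial ribosome list was lower too (-0.35, adjusted p = 2.4e-05, with mRpL4 higher at 1.62 ± 0.24). Each of the 3 was lost with an estimated correlation (adjusted p = 0.97, 0.96 and 0.999). The zygotic list had medians of -0.21 at 1-2h (adjusted p = 0.045) and 0.21 at 2-3h (adjusted p = 0.033; 0.999 in both with an estimated correlation).

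**Figure D3:**
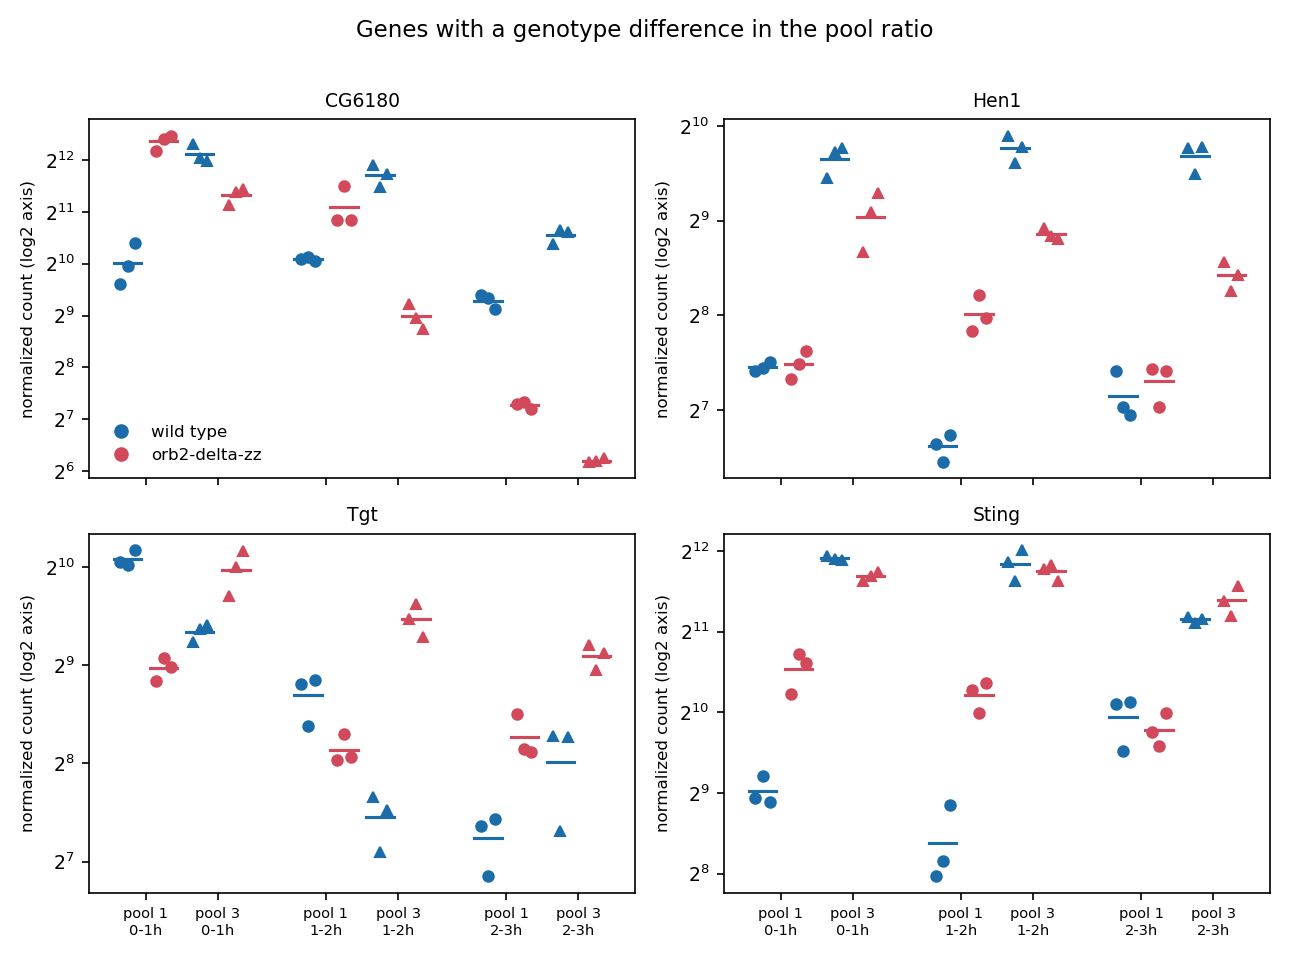
Normalized counts (log2 axis) of CG6180, Hen1, Tgt and Sting in pools 1 and 3 of each gradient, wild type and orb2-delta-zz, at the 3 times. For CG6180 at 0-1h the wild-type means were 1039.9 in pool 1 and 4440.1 in pool 3, and the orb2-delta-zz means 5257 and 2562.

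The ratio differed in 39 genes at 0-1h (21 higher and 18 lower), in 40 at 1-2h (11 and 29) and in 13 at 2-3h (5 and 8). The values per gradient did not overlap for 15.4%, 14.1% and 30.3% of genes, where chance gives 10%. Simulated 2-fold changes of the ratio, with noise independent between libraries and no block, were called in 59.0%, 35.9% and 8.20% of genes. Array weights gave 2370, 185 and 438 genes. With the gradient as a block, which pairs its pools, 21 genes were called at 0-1h and 510 at 2-3h, of which 271 were higher and 239 lower. Other scaling moved the split at 0-1h to 32 higher and 49 lower with quantile normalization and 31 and 51 with upper-quartile scaling. At 1-2h it was 36 and 56 with log2(TPM + 1), 48 and 56 with quantile normalization and 49 and 47 with upper-quartile scaling, and at 2-3h 139 and 74, 264 and 156, and 174 and 112 in the same order. Every gene named at 2-3h lost its call without some single gradient. By limma 0 genes were left there without orb2-delta-zz replicate 1 or 2 or wild-type replicate 3, against 1232 genes under an unadjusted p of 0.05 with all gradients.

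What the pools held was described from wild type alone. Relative to other genes, long mRNAs had a higher pool 3 to pool 1 ratio than short ones and small RNAs. At 0-1h Bicra (FBgn0039633, 3R, 29063040 to 29108948), a gene of a chromatin remodelling complex, had 218 ± 11.4 normalized counts in pool 1 and 39259 ± 5254 in pool 3 (log2 ratio 7.48 ± 0.14, adjusted p = 1e-11). It was followed by poe (FBgn0011230; 7.30), mask (FBgn0043884; 7.26), rno (FBgn0035106; 7.24) and shot, which links actin and microtubules (FBgn0013733; 7.22). Spt6 (FBgn0028982, X, 6267797 to 6274984), of transcription elongation, had log2 ratios of 6.64 ± 0.16 at 1-2h and 5.42 ± 0.17 at 2-3h, and Taf1 (FBgn0010355) 6.82 at 1-2h. At the other end, RNaseMRP:RNA (FBgn0065098) fell from 140474 ± 87632 in pool 1 to 534 ± 72.3 in pool 3 at 0-1h (-7.80 ± 0.48). For snoRNA:SC35-a (FBgn0263468) the means went from 19503 ± 2638 to 19.3 ± 3.51 at 2-3h (-9.91 ± 0.26, adjusted p = 3.5e-11).

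Ribosomal protein mRNAs were lower in pool 3 than in pool 1 in 83 of 85, 83 of 85 and 84 of 87 members at the 3 times (medians -3.15, -4.05 and -4.56, adjusted p = 2e-18, 3.3e-28 and 8.2e-44; 0.999, 0.95 and 0.95 with an estimated correlation). Among them RpS2 was at -4.12, -5.11 and -5.71. Small nuclear and nucleolar RNAs were lower in 71 of 71, 74 of 74 and 84 of 84 (medians -5.10, -6.14 and -6.72, adjusted p = 1.4e-11, 4.5e-22 and 7.3e-41; 0.999, 0.95 and 0.39 with an estimated correlation). Cytoskeleton and cellularisation mRNAs were higher in pool 3 in 17 of 23, 17 of 23 and 17 of 24 (medians 2.51, 2.25 and 1.13, adjusted p = 0.0013, 0.00096 and 4.4e-05; 0.97, 0.97 and 0.96 with an estimated correlation). Here betaTub56D was at 3.20, 2.69 and 1.57 and Act5C at 2.07, 1.93 and 1.74. Mitochondrial ribosome mRNAs were lower in 68 of 71 at 0-1h (median -1.54, adjusted p = 6.6e-11), in 57 at 1-2h (-1.29, adjusted p = 2.6e-08; 0.999 at both with an estimated correlation) and in 26 at 2-3h (-0.29, adjusted p = 0.16). Translation factors were lower in 32 of 44, 33 of 45 and 29 of 47 (adjusted p = 0.0037, 0.00029 and 5.4e-05; 0.999 at all 3 with an estimated correlation), and eEF1alpha1 was at -2.34, -3.22 and -4.06. Zygotic mRNAs were higher in 38 of 60 at 0-1h (median 1.47, adjusted p = 0.0025; 0.999 with an estimated correlation), but at 2-3h 15 were higher and 17 lower (adjusted p = 0.72). The translational repressor mRNA smg had ratios of 4.75, 3.92 and 1.20, and CycB of 3.45, 2.26 and 0.59. The ratio of orb2 was 0.66 ± 0.18 at 0-1h (adjusted p = 0.00520), a call lost with quantile normalization (0.38) and upper-quartile scaling (0.23).

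**Figure D4:**
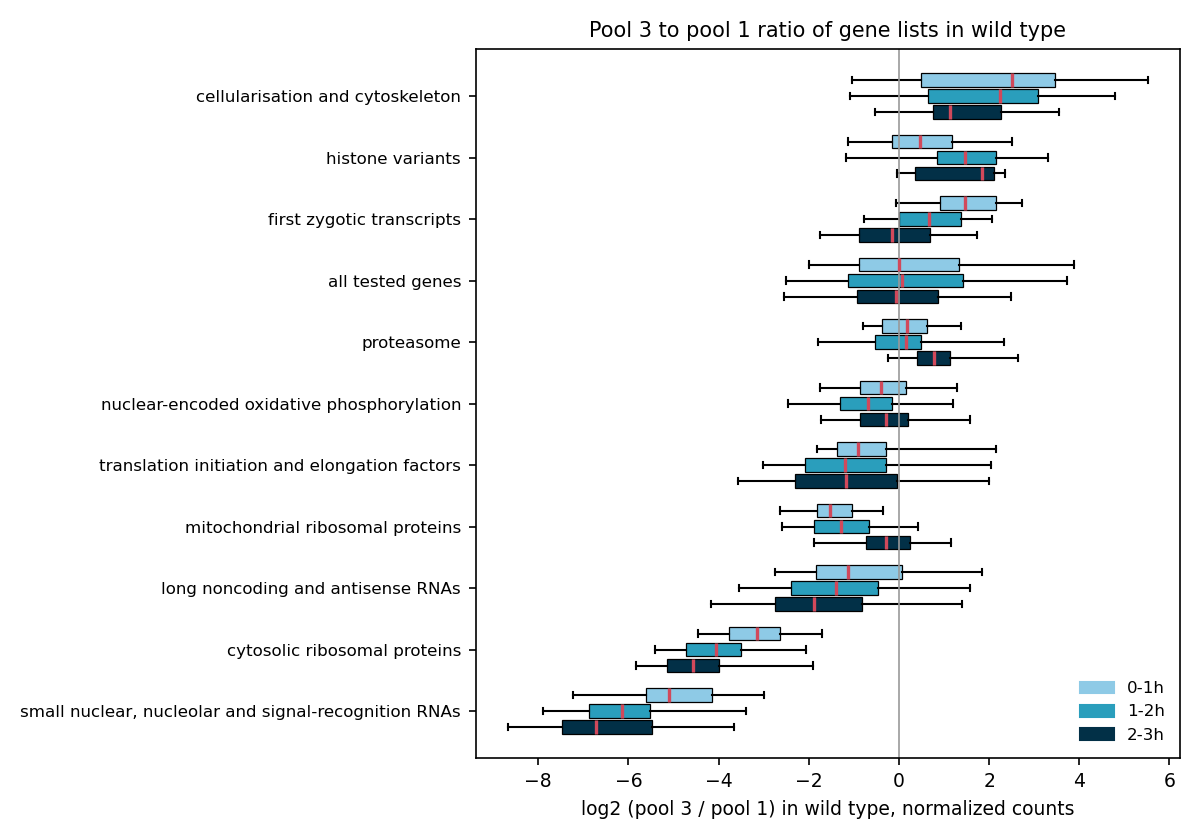
Log2 pool 3 to pool 1 ratio in wild type for the members of each gene list at the 3 times (boxes the quartiles, lines the median, whiskers the 5th to 95th percentiles). Medians for cytosolic ribosomal proteins were -3.15, -4.05 and -4.56, and for cytoskeleton genes 2.51, 2.25 and 1.13.

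In wild type the ratio was above 0 in 2996 genes and below 0 in 3061 of 7533 at 0-1h, in 3070 and 3071 of 8294 at 1-2h and in 2802 and 2590 of 9554 at 2-3h. The pools did not overlap for 83.6%, 75.5% and 60.8% of genes. The sign of a ratio depended on the scaling. TPM moved the median ratio of all genes by 1.29, 1.74 and 2.27, with 5052 higher and 549 lower at 0-1h, 5667 and 598 at 1-2h and 7091 and 275 at 2-3h. Upper-quartile scaling moved it by -0.43, -0.45 and -0.48, with 2305 and 3886, 2489 and 3853, and 2016 and 4019. Relative to the median of all genes, the medians of the ribosomal protein, small RNA and cytoskeleton lists kept their sign under all 3 other scalings, as did those of the translation factors. For upper-quartile scaling and TPM this was nearly given in advance. Both change all genes of a library by 1 factor, apart from a constant per gene, the added 1 and the filter. Quantile normalization alone could have turned the sign. For the mitochondrial ribosome at 2-3h camera turned from lower (adjusted p = 0.16) to higher with log2(TPM + 1) (adjusted p = 0.025).

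The last comparison followed the maternal-to-zygotic transition itself, as the change from 0-1h to 2-3h in wild type, measured in TPM, which is scaled within each library. Zygotic genes rose in both pools, and by camera the maternal list fell past other genes in pool 3 (adjusted p = 1.2e-05, but 0.999 with an estimated correlation). In pool 1, 57 of 60 members of the zygotic list rose and 1 fell, and the same counts held in pool 3. The pair-rule gene eve (FBgn0000606, 2R, 9979319 to 9980795) went from 1.02 ± 0.12 to 73.6 ± 31.5 TPM in pool 1 (log2 change 5.13 ± 0.25, adjusted p = 9.8e-13). Next to it were the Notch target E(spl)m5-HLH (FBgn0002631), from 4.52 ± 1.74 to 230.1 ± 74.3 (5.37 ± 0.29), lncRNA:roX1 (FBgn0019661; 5.07) and Z600 (FBgn0004052; 4.74) in pool 1. In pool 3 the largest rises were those of the pair-rule gene opa (FBgn0003002; 4.98 ± 0.22), danr (FBgn0039283; 4.99), dan (FBgn0039286; 4.94), nkd (FBgn0002945; 4.83), ci (FBgn0004859; 4.78) and SoxN (FBgn0029123; 4.70).

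Among maternal RNAs, dhd (FBgn0011761, X, 5312171 to 5313125), the thioredoxin that acts on sperm chromatin, fell from 7282 ± 451 to 12.6 ± 2.26 TPM in pool 1 (-9.08 ± 0.20, adjusted p = 5.4e-17) and from 4466 ± 417 to 20.5 ± 0.270 in pool 3 (-7.70). The localisation factor gene exu (FBgn0000615, 2R, 20667427 to 20671083) fell from 797 ± 241 to 7.29 ± 1.28 in pool 1 (-6.56) and from 697 ± 29.5 to 6.44 ± 0.856 in pool 3 (-6.56). Hsp26 (FBgn0001225) was among the lowest in pool 1 (-6.89), and BicC (FBgn0000182; -7.26) and the maternal tubulin gene alphaTub67C (FBgn0087040; -6.51) in pool 3. In pools 1 and 3 GstD1 (FBgn0001149) changed by -7.61 and -6.47, osk by -3.51 and -5.21, bru1 by -5.47 and -5.80 and Hsp83 by -4.58 and -3.48. For orb2 the change was -2.09 ± 0.30 in pool 1 (9.12 ± 5.98 to 1.16 ± 0.398 TPM, adjusted p = 2.2e-06) and -1.88 in pool 3 (31.5 ± 0.942 to 8.13 ± 3.11 TPM). Of the classic maternal transcripts, 20 of 27 fell in pool 1 and 24 in pool 3, with 1 rising in each. Of the germ-plasm genes 22 of 26 fell in pool 1 and 17 in pool 3. Replication-dependent histone mRNAs rose in 19 of 21 in pool 3 (adjusted p = 4.5e-06 by camera; 0.95 with an estimated correlation). In pool 1 2 rose and 17 fell, with a median of -1.70 close to that of all genes (adjusted p = 0.23).

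With a median change of -1.36 over all genes in pool 1 and -0.29 in pool 3, 1088 of 7294 genes rose and 4999 fell in pool 1, and 1550 rose and 3163 fell in pool 3. Only genes listed at all 3 times were tested. The tables listed 2420 genes at 2-3h and not at 0-1h, and 75 at 0-1h and not at 2-3h. RNAs first listed later are therefore missing from these counts and from the rises named. Relative to those medians, the zygotic list rose by 4.83 and 4.09 (adjusted p = 1.4e-46 and 3.4e-33; 0.39 and 0.68 with an estimated correlation). The maternal list was at -0.42 (adjusted p = 0.43) and -1.79 (adjusted p = 1.2e-05; 0.999 with an estimated correlation). The germ-plasm list was at -0.81 (adjusted p = 0.17) and -2.0 (adjusted p = 0.00095; 0.999 with an estimated correlation). Quantile normalization moved the medians of all genes by 1.47 and 0.45 and gave 2756 rising and 2903 falling genes in pool 1 and 2899 and 2574 in pool 3. Upper-quartile scaling moved them by 1.72 and 0.27 and gave 3505 and 2430, and 2478 and 2887. Late-embryo markers, which stood apart in wild-type replicate 2 at 2-3h, rose in 3 of 9 members in pool 1 and 5 of 9 in pool 3.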

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

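The tests chosen only after the result was seen are those of low read numbers, of chromosome 3, of late embryos held back by wild-type females and of the 2 wild-type gradients at 2-3h, and the regroupings of libraries. Of the genes whose genotype difference was not the same in pool 1 and pool 3 by the interaction term of the model (39, 40 and 13 at the 3 times), 27 gene and time combinations with the largest differences are given, picked by the rule for named genes. The value for each is that interaction, with the genotype difference in pool 1 and in pool 3 after it.

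At 0-1h Tgt had an interaction of 1.72 (-1.11 in pool 1 and 0.61 in pool 3), CG9356 of 1.52 (-1.27 and 0.25), CG31650 of 1.416 (-1.18 and 0.23) and GstT1 of 1.24 (-0.80 and 0.43). In the other direction CG6180 had -3.16 (2.37 and -0.79), Sting -1.73 (1.51 and -0.22), CG9328 -1.70 (1.31 and -0.39), CG12547 -1.31 (1.39 and 0.08) and CBP -1.22 (1.14 and -0.07). At 1-2h the interaction was 2.56 for Tgt (-0.55 and 2.02), 2.15 for CG4935 (0.00 and 2.15), 2.08 for CG17598 (-1.40 and 0.68) and 1.72 for CG9577 (0.65 and 2.36). It was -3.70 for CG6180 (0.97 and -2.73), -2.28 for Hen1 (1.38 and -0.90), -2.21 for CG8187 (1.21 and -0.99), -2.08 for ecd (1.39 and -0.69) and -2.06 for CG17568 (1.33 and -0.74). At 2-3h tbc had 2.96 (-0.96 and 2.00), Kank 2.22 (-0.88 and 1.34), mRpL4 1.62 (-1.28 and 0.34) and gem 1.46 (-1.50 and -0.04). GstE8 had -2.84 (3.68 and 0.83), CG5532 -2.42 (2.44 and 0.02), CG6180 -2.33 (-2.0 and -4.33), osi -2.01 (1.22 and -0.79) and Nepl3 -1.91 (1.03 and -0.88). None of these reversed under an alternative, but calls were lost. At 0-1h GstT1 and CG12547 were not called without orb2-delta-zz replicate 2, orb2-delta-zz replicate 3, wild-type replicate 2 or wild-type replicate 3, nor CBP without the former 3, and GstT1, CG12547, CBP, CG31650 and CG9328 were not called with log2(TPM + 1). At 1-2h CG9577 was not called without any 1 of the orb2-delta-zz replicates, nor CG4935 and CG17568 without orb2-delta-zz replicate 2. At 2-3h none of the 9 was called without orb2-delta-zz replicate 1, orb2-delta-zz replicate 2 or wild-type replicate 3, and CG6180 alone was called without orb2-delta-zz replicate 3, and CG6180 and CG5532 without wild-type replicate 1.

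The first pattern is the set of 95 genes that differed between the genotypes in the same direction at all 3 times in both pools. A single stretch of chromosome around orb2 that differs between the stocks is argued against as the source of most of these genes. Only 2.11% of them lay on 3L within 5 Mb of orb2, where 7.80% of tested genes lie. It stays open for single genes in that stretch, such as tut and Dscam4, both far lower in orb2-delta-zz. Low read numbers are argued against, although the median of the mean normalized counts was 611 (lower than the 25th percentile of tested genes, 658), since in each pool and direction genes were called at all 3 times at least 21.7 times as often as independent calls would give. Stock differences on other chromosomes may contribute, as 22.1% of the genes lay on chromosome 3 against 43.4% of tested genes (Fisher's exact test, one-sided, p = 1.01e-05) and against 39.4% of the other called genes. Linked blocks cannot be told apart from an effect of the genotype, because 18 of the genes had another within 50 kb (median of 10000 random draws 11, share of draws at least as high 0.0899), and an effect of the ZZ domain itself stays open, as the design has 1 mutant stock and 1 control stock.

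The second pattern is the lower level of the first zygotic transcripts in orb2-delta-zz at every time. The 2 wild-type gradients at 2-3h that stand apart are argued against as the whole cause, since at 0-1h and 1-2h, which share no library with 2-3h, the list was lower in 4 of 4 camera tests, with 27 to 49 members called, although each list call was lost with an estimated correlation (adjusted p = 0.68 to 0.95). Late embryos held back by wild-type females are argued against as the whole cause at 1-2h. Without wild-type replicate 2 the late-embryo medians at 1-2h and 2-3h were 0.917 to 3.38 higher in orb2-delta-zz, while the zygotic medians stayed at -0.635 to -1.23. At 2-3h this test cannot decide, because wild-type replicate 2 had the lowest zygotic level of its genotype in each pool. Its zygotic deviations were 0.12 and 0.15, against 0.45 to 0.75 in wild-type replicates 1 and 3, so leaving it out could only widen the difference. At 0-1h late embryos cannot be told apart from an effect on zygotic transcription, as the late-embryo medians were 0.958 and 0.689 but -0.308 and -0.918 without orb2-delta-zz replicate 1. Younger or slower embryos cannot be told apart from it either. The genotype differences of other genes went against the wild-type change with time at 1-2h (correlations across genes of -0.414 and -0.515 in pools 1 and 3). The correlations were weaker at 0-1h (-0.046 and -0.184) and 2-3h (-0.085 and -0.063), where the change compared lies outside the window. At 2-3h other genes that rose from 0-1h to 1-2h in wild type had median genotype differences of -0.62 and -0.79 (all genes 0.08 and 0.02). Those that fell had -0.15 and -0.50, although the maternal and germ-plasm lists were higher in orb2-delta-zz in that window. How collections were staged is not given in the sources used here.

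The third pattern is the large difference between the pools in wild type. Pool 3 holding RNAs that carry more ribosomes than those of pool 1 is a candidate explanation, since the ratio rose with coding length at every time (Spearman correlation across coding genes, which are not independent, 0.578 at 0-1h, 0.470 at 1-2h and 0.362 at 2-3h). It rose about as much with transcript length (0.585, 0.469 and 0.330), so the number of ribosomes and the length of the RNA itself are not separated by this. The authors' length correction is part of both deposited tables, so its share in this was not tested. Which gradient fractions each pool covers was not measured here, so the ratio is no direct measure of translation.

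The 6 samples of each comparison allow 10 splits into 3 and 3, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, reached the real count. At 0-1h the real counts were 756 in pool 1, 571 in pool 3, 39 for the genotype difference in the ratio and 6057 for the wild-type ratio, with 0 by limma as the highest other in each. At 1-2h they were 948, 711, 40 and 6141, again with 0 as the highest other in each. At 2-3h they were 2280 (highest other 1), 1403 (958), 13 (0) and 5392 (0), and for the change with time 6087 (0) and 4713 (1). The split with 958 genes in pool 3 set wild-type replicates 1 and 3 and orb2-delta-zz replicate 1 against the rest, a structure of the samples that the genotype does not explain. It follows late-embryo RNA, whose deviations in pool 3 were -1.68, -2.86 and -0.15 in these gradients. In wild-type replicate 2 and orb2-delta-zz replicates 2 and 3 they were 2.27, 2.05 and 0.89. How much of the real count of 1403 it accounts for was not tested. At unadjusted p under 0.05 the real splits had 1593, 1209, 552 and 6128 genes at 0-1h, 2240, 1701, 484 and 6240 at 1-2h, 3690, 3101, 1232 and 5774 at 2-3h, and 6143 and 4927 for the change with time.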

How the results depend on the processing

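The alternatives that leave out 2 gradients together were chosen only after the result was seen. No named gene that was called changed direction under an alternative. Of the called lists 3 did, all without wild-type replicate 1 at 0-1h, and none of them was called in the other direction. Cellularisation and the cytoskeleton with time in pool 1 were up by camera (adjusted p 0.027) and down by fry (0.12), which do not conflict. Camera compares the list with other genes and fry compares it with no change. The median change of the list was -0.24, against -1.36 for all genes. Without wild-type replicate 1 at 0-1h the cytosolic and mitochondrial ribosomal proteins turned from higher in pool 1 (0.026 and 0.043) to lower (0.18 and 0.50), with other leave-outs between 4.4e-07 and 0.29 and between 4.5e-06 and 0.38, and the small nuclear RNAs from lower in the ratio (0.0028) to higher (0.20), with others between 4.3e-07 and 0.16. Among all genes the sign of the wild-type ratio depended on the scaling. With log2(TPM + 1) 3410 of the 6057 genes called at 0-1h, 3539 of 6141 at 1-2h and 3043 of 5392 at 2-3h were called in the same direction. The wild-type ratio and the change with time kept their counts of genes within 1.5 times under every alternative. The settings log2(value + 8), a mean of at least 100, no filter and a fold of at least 1.5 did so for all results they were run on (13, 13, 15 and 20). Other genotype counts moved further, and beyond the smaller number of samples in leave-outs and in fits of 6 libraries the cause was not tested. The balance of calls moved as well, from 423 higher and 333 lower in pool 1 at 0-1h to 86 and 129 with log2(TPM + 1). With 3 gradients per group and noise independent between libraries, simulated 2-fold changes of the ratio were called in 59.0%, 35.9% and 8.20% of genes at the 3 times. The gradient as a block was not simulated. Of 174 results of named genes, orb2 included, 174 kept their side of the threshold with the replicate block and with no filter, 172 with quantile normalization and 173 with upper-quartile scaling. With log2(TPM + 1), run on fewer of them, 122 kept it, 7 lost a call and 2 gained one.

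Array weights gave 4043 genes in pool 1, 3205 in pool 3 and 2370 for the ratio at 0-1h, 1646 in pool 3 and 185 for the ratio at 1-2h, and 4808 in pool 3 and 438 for the ratio at 2-3h. With log2(TPM + 1) there were 215, 330 and 14 at 0-1h, 92 for the ratio at 1-2h, and 2565 in pool 3 and 213 for the ratio at 2-3h. The same setting gave overlaps of 147 (pool 1, 0-1h and 1-2h), 106 (pool 1, 0-1h and 2-3h) and 526 (pool 3, 1-2h and 2-3h), and an orb2 difference in pool 1 at 2-3h of 0.66, no longer called. Quantile normalization gave 81, 104 and 420 genes for the ratio at the 3 times, and upper-quartile scaling 82, 96 and 286 and, in pool 3 at 2-3h, 2206. With only the 6 libraries compared there were 386 genes in pool 1 at 0-1h and 611 at 1-2h, and orb2 at 1.06 was no longer called. With the replicate or gradient as a block there were 21 genes for the ratio at 0-1h, 3950 in pool 1 and 3301 in pool 3 at 2-3h, and 510 for the ratio at 2-3h. Of 252 list tests camera called 83 at the preset correlation of 0.01 and 0 with an estimated correlation. Fry, which asks a different question (a list against no change), called 83, of which 53 were the same. Camera called 79 with quantile normalization (64 the same) and 90 with the block (83 the same). With log2(TPM + 1), not run for the change with time, camera lost 6 calls and gained 12.

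Leaving out wild-type replicates 1 and 3 at 2-3h left 1 wild-type gradient, assumed to vary like the other groups, and gave 161 genes in pool 1, 92 in pool 3 and 1 for the ratio, and an orb2 difference of 0.89, no longer called. Leaving out wild-type replicate 2 and orb2-delta-zz replicate 3 at 1-2h gave 24 for the ratio. Leaving out replicate 2 of both genotypes at 2-3h gave 0 for the ratio by limma and an orb2 difference of 1.38.

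Without 1 gradient the counts at 0-1h ran from 346 to 1150 in pool 1, with 350 without orb2-delta-zz replicate 2, 355 without its replicate 3 and 346 without wild-type replicate 2. They ran from 256 to 884 in pool 3, with 294 and 304 without orb2-delta-zz replicates 2 and 3 and 256 and 333 without wild-type replicates 2 and 3. Without orb2-delta-zz replicate 1 they were 1150 and 884. For the ratio at 0-1h they ran from 9 to 42, with 9 and 10 without orb2-delta-zz replicates 2 and 3 and 10 and 15 without wild-type replicates 2 and 3. At 1-2h they ran from 423 to 833 in pool 1 (423 and 581 without orb2-delta-zz replicates 2 and 3, 527 without wild-type replicate 1) and from 422 to 794 in pool 3 (422, 423 and 470 without orb2-delta-zz replicates 1, 2 and 3, 461 without wild-type replicate 1). The ratio there ran from 15 to 48 (24, 15 and 17 without orb2-delta-zz replicates 1, 2 and 3, 17 without wild-type replicate 1). At 2-3h they ran from 883 to 3169 in pool 1 (1349 and 973 without orb2-delta-zz replicates 2 and 3, 883 and 978 without wild-type replicates 1 and 3) and from 376 to 3172 in pool 3 (706 and 403 without orb2-delta-zz replicates 2 and 3, and 376, 3172 and 553 without wild-type replicates 1, 2 and 3). The ratio at 2-3h ran from 0 to 16 by limma (0, 0 and 1 without orb2-delta-zz replicates 1, 2 and 3, 2 and 0 without wild-type replicates 1 and 3), against 1232 genes at an unadjusted p under 0.05 with all gradients. The wild-type ratio ran from 5444 to 6261, 5606 to 6122 and 4357 to 5404, the change with time from 5849 to 6202 in pool 1 and from 4246 to 5031 in pool 3, and orb2 in pool 1 at 2-3h from 0.72 to 1.29. In pool 1 at 2-3h orb2 was not called without orb2-delta-zz replicate 3, wild-type replicate 1 or wild-type replicate 3.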

Other observations

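The tests in this part were fixed before the data were examined. At 2-3h the embryonic linker histone mRNA BigH1, a maternal product of the early nuclei, was higher in orb2-delta-zz (log2 difference 2.09 ± 0.33 in pool 1 and 2.05 in pool 3), while 7 of 23 replication-dependent histone mRNAs were lower in pool 1 and none was higher. The lowest of those was His1:CG33852 (-1.16 ± 0.18). The list median was -0.21 in pool 1 (adjusted p = 0.0091) and -0.36 in pool 3 (adjusted p = 0.015), and 0.999 in both with an estimated correlation. It stayed below 0 at 2-3h under the 3 other scalings. Of the 10 histone variants, His4r was also higher in pool 1 (0.90) and 1 was lower, and the list was called in neither pool (adjusted p = 0.48 and 0.56). In the same window the cell-cycle list had 7 members higher and 3 lower of 27 in pool 1, and 6 and 2 in pool 3 (adjusted p = 0.17 and 0.40). CycA was higher in pool 1 (0.74 ± 0.17) and CycD in pool 3 (1.07 ± 0.20), and CycB3 was lower in pool 1 (-0.65 ± 0.19). The Cdc25 inhibitor mRNA trbl was lower in both (-1.02 ± 0.20 and -0.83). Whether these changes belong together was not tested.

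Cytoskeleton and cellularisation genes moved both ways at 2-3h. The maternal tubulin mRNA alphaTub67C was higher (1.15 ± 0.21 and 1.17) and the actin nucleator mRNA spir was higher in pool 3 (1.89 ± 0.36), while the cell adhesion gene Nrt (-1.01 ± 0.28) and the anillin gene scra (-0.83 ± 0.22) were lower in pool 1. Of 24 members 2 were higher and 3 lower in pool 1, and 3 and 0 in pool 3 (adjusted p = 0.87 in both). At 1-2h Nrt was lower in both pools (-0.85 and -0.89) and scra in pool 1 (-0.57), and at 0-1h alphaTub84B was higher in pool 1 (0.61 ± 0.13). In the cell-cycle list grp was lower in pool 1 at 0-1h (-0.41), where 1 member was higher and 2 were lower, and trbl in pool 3 at 1-2h (-0.58 ± 0.15).

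Among 87 cytosolic ribosomal protein mRNAs RpLP2 stood alone. It was the only member called at 1-2h (1.54 ± 0.16 in pool 1, 0.86 in pool 3) and at 2-3h (1.504 ± 0.15 and 0.63), and no member was called at 0-1h. The list was called higher in pool 1 at 0-1h (median 0.20, adjusted p = 0.026) and lower in pool 3 at 2-3h (-0.13, adjusted p = 0.011), both 0.999 with an estimated correlation. Without wild-type replicate 1 the list at 0-1h turned to lower and was not called (camera adjusted p = 0.18). Its ratio was lower in orb2-delta-zz at 2-3h (-0.19, adjusted p = 0.0018), as was that of the translation factors (-0.22, adjusted p = 0.0017), with 0.999 for each under an estimated correlation and medians below 0 under the other scalings. Of the translation factors eIF4EHP, a cap-binding repressor mRNA, was higher in pool 1 at 0-1h (0.69 ± 0.11) and 1-2h (0.82 ± 0.17), where 1 of 44 and 4 of 45 members were higher and none was lower. At 2-3h 7 of 47 were higher and 1 lower in pool 1 (eRF3 0.80 ± 0.20), and 4 were lower in pool 3, with eIF4E3 at -4.04 ± 0.51 and eIF4H2 at -2.46.

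Of the small nuclear, nucleolar and signal-recognition RNAs none of 71 was called at 0-1h. At 1-2h 1 of 74 was higher and 1 lower in pool 1, and 2 and 1 in pool 3, and at 2-3h 2 of 84 were higher and 3 lower in each pool. The list was called in pool 1 at 1-2h alone (median -0.14, adjusted p = 0.0091; 0.999 with an estimated correlation). The copies of the U2 gene moved in opposite directions, snRNA:U2:34ABb by 1.11 and 1.40 at 1-2h and 1.49 and 0.98 at 2-3h, and snRNA:U2:34ABa by -1.30 and -1.26, then -0.90 and -1.32. How reads shared between the copies were assigned was not tested. The ratio of the small RNA list at 0-1h was lower in orb2-delta-zz (-0.41, adjusted p = 0.0028), as was that of the replication-dependent histones (-0.23, adjusted p = 0.0037), both 0.999 with an estimated correlation. Without wild-type replicate 1 the small RNA ratio turned to higher and was not called (camera adjusted p = 0.20).

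Few markers of the mothers' own tissues were in the tables. A gene at 0 in 1 library is missing from them, so this does not measure how much such RNA was present. Of the egg-shell and follicle-cell markers 1, 2 and 4 were tested at the 3 times, and mirr, which embryos express too, was lower at 1-2h (-1.17 ± 0.27 and -1.55) and in pool 1 at 2-3h (-1.41 ± 0.35). Of the adult fat body, gut and sperm markers 3 were tested, at 2-3h alone, and limma called 0 of them in either pool. Of mitochondrially encoded RNAs, searched by the symbol prefix mt:, the tables gave 0 genes to test, and they list only genes above 0 in all 12 libraries of a time.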
